A study of Rattus norvegicus with 4 samples.

How the data were processed

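Lungs of 8 rats were dissociated with an enzyme kit made for mouse lung, and the cells of 4 animals were tagged with lipid-anchored oligonucleotides (CellPlex) and captured together as 1 pool, per the labels' protocols. There were 2 pools, with 3' gene expression libraries of version 3.1 chemistry read on a NovaSeq. The deposited values were counts of unique molecular identifiers (UMIs) per gene and cell, 1 filtered matrix per animal, already assigned to animals by tag. The submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10, whereas all 32883 genes in the files carry rat Ensembl identifiers, so mm10 was not the build of these counts and the rat annotation release is not given in the sources used here. No coordinates are printed for that reason. Symbols were those of the files. Of these, 17538 (53.3%) were also symbols of the RefSeq annotation of assembly GRCr8, which was used for nothing else, and 2672 identifiers shared a symbol with another and were told apart by identifier.

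Labels gave only the pool of each matrix, so each animal's group was read from the deposited table of tags. That table put 2 animals in each of 4 groups. A no-isoflurane group appeared there for the first time, and its comparison with the sham group was added after the table had been read. In 17274 of 17476 barcodes the tag of the animal had the most counts of the pool's tags. All 202 others were among the 1536 barcodes of ultrasound 1 and had more counts of the tag of healthy 1. They were kept as deposited, and no setting left out only these barcodes. Whether they were cells of healthy 1 was not tested, a limit on every comparison with ultrasound animals. Group and pool together gave 5 design columns of rank 4, so no pool term could be fitted.

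Cells with at least 200 genes and at most 20% mitochondrial UMIs were taken, which removed 1915 barcodes. Doublets were predicted per pool with scrublet in scanpy (version 1.11.5, expected rate 0.06), which called 334 of 10349 cells in pool 3 (3.23%) and 96 of 5212 in pool 4 (1.84%), and these were removed. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was clustered with the Leiden algorithm (leidenalg 0.10.2, resolution 1.0). A cluster of at least 20 cells took the name of the best of 30 marker lists if its score was at least 0.75 and led the next by 0.5, with at least 3 markers detected in 20% of its cells. It stayed unnamed if, among its 10 genes of highest ratio, another list or cycling genes had more markers than the best list, or if none of that list's was there and the median UMI ratio to the animals' median was under 1/3. The score was the mean log2 ratio of marker CPM to the other cells, with 5 CPM added. The lists were fixed before the data were examined, the thresholds afterwards.

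UMIs were summed per animal and class, for animals with at least 20 cells of the class, and a class was tested where both groups kept 2 animals. Sums were compared with edgeR (version 4.0.16, R 4.3.3), using filterByExpr, TMM normalization, a robust quasi-likelihood fit of all groups together and Benjamini-Hochberg adjustment per class and comparison at 0.05. In all, 23 gene lists fixed beforehand were tested in monocytes and macrophages with camera (limma 3.58.1) at a preset correlation between genes of 0.01, for lists with at least 5 tested members. Class shares were compared by exact two-sided permutation tests over 6 splits of the animals for 13 classes. Genes sharing a symbol or reads with close copies, such as the RT1 and immunoglobulin families, are uncertain.

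Named genes followed a rule fixed in advance for sham against healthy and ultrasound against sham. It took, per monocyte or macrophage class, the 4 genes per direction with the smallest adjusted p, up to 3 called members of each list or otherwise up to 2 with the smallest p as values, and 2 genes per direction in the 3 other classes with most calls. Where no gene passed in a direction it took the 2 with the smallest p, and it always took Il1b, Tnf, Ccl2, Nlrp3 and Spp1. Genes without a symbol and mitochondrial and haemoglobin genes were counted but not named. The text prints the called genes, most of the 5 always taken, and examples from lists that passed. Xenobiotic genes of the endothelium other than Cyp1a1, Tiparp and Nqo1, and the comparisons of these with healthy animals in ultrasound animals, were chosen after their values were seen.

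Alternatives fixed beforehand were DESeq2 size factors in edgeR, the DESeq2 Wald test (version 1.42.0), no filter on low counts, a fit of only the 2 groups compared, each animal left out, doublets kept, at most 10% mitochondrial UMIs, at least 50 cells, sums thinned to the lowest total, clustering at resolution 0.5, other denominators and a count model for shares, and an estimated correlation for lists. Joining or exchanging sham and no-isoflurane animals and leaving out haemoglobin genes were added after the data were seen. In simulated data with 200 changed genes and 10 draws, the test recovered 6.7%, 51.5% and 88.5% of genes changed 1.5-fold, 2-fold and 4-fold for sham against healthy alveolar macrophages, and 8.5%, 50.4% and 88.3% for ultrasound against sham nonclassical monocytes. For the small class of interstitial macrophages the last comparison gave 0.6%, 4.9% and 55.8%. Of the simulated calls 9.7%, 10.6% and 15.1% were false, above the nominal share, so some calls at the threshold are chance. Free RNA was not subtracted.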

Results

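Lung cells from 8 rats were profiled by droplet-based single-cell RNA sequencing. SuHx is a rat model of pulmonary hypertension made with a vascular endothelial growth factor receptor blocker and low oxygen. For 2 weeks the spleens of SuHx animals had been treated with focused ultrasound or with a sham procedure, and healthy animals of like age were the controls. The deposited table of sample tags placed 2 animals in each of 4 groups, which were healthy, SuHx listed as without isoflurane (an inhaled anaesthetic), SuHx sham and SuHx ultrasound. Animals are numbered 1 and 2 within a group. Cells of 4 animals were pooled before capture. Pool 3 held the sham and no-isoflurane animals and pool 4 the healthy and ultrasound animals. Sham against healthy and ultrasound against sham therefore crossed the pools, and pool and group cannot be told apart in these comparisons, whereas ultrasound against healthy and sham against no isoflurane lay within a pool.

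The files held 17476 cell barcodes, 1462 to 3037 per animal, with 10482615 to 27193404 unique molecular identifiers (UMIs) assigned to genes per animal. After filtering, 15131 cells and 124615753 UMIs were kept. Healthy 1 and healthy 2 kept the fewest cells, 766 and 1157, and 51.0% and 19.3% of their barcodes had over 20% mitochondrial UMIs. In the SuHx animals this share was between 3.06% and 10.4%. The median kept cell had 4348 UMIs in ultrasound 2 and 14629 in healthy 2, the lowest and highest of the 8 animals. Clusters were named from marker lists fixed before the data were examined, and each class name below means clusters whose cells resembled that type. Log2 fold changes are edgeR estimates ± SE on counts summed per animal and class, with n = 2 animals per group, and adjusted p are Benjamini-Hochberg values of edgeR's quasi-likelihood test unless another test is named. For a gene list, the median is that of its members' log2 fold changes, and the adjusted p is camera's, first at a preset correlation between genes and then at one estimated from the data. Levels are summed UMIs scaled to a common total (CPM) and given as mean ± SD.

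B cells, T cells, neutrophils and nonclassical monocytes made up larger shares of the recovered cells in sham SuHx lungs than in healthy lungs, and 2 endothelial classes smaller ones. B cells were 1.37 ± 0.835% (SD, n = 2) of kept cells in healthy and 10.3 ± 4.73% in sham animals, and T cells 0.955 ± 0.495% and 8.41 ± 1.33%. Neutrophils were 2.37 ± 0.901% and 11.8 ± 1.83%. Nonclassical monocytes, which patrol the vessel wall, were 5.29 ± 1.57% and 22.3 ± 11.4%. Aerocytes, the capillary endothelial cells specialised for gas exchange, were 8.42 ± 3.23% and 1.91 ± 1.03%, and venous endothelial cells 4.04 ± 2.78% and 0.575 ± 0.430%. In edgeR's test on cell counts, an alternative chosen beforehand, these had adjusted p of 0.00548, 0.00548, 0.0178, 0.0238, 0.0238 and 0.00749 in that order. B and T cells were higher, and venous endothelium lower, in all pool 3 than in all pool 4 animals. Leaving out 1 animal moved the difference between the means over 1.5 times for nonclassical monocytes, from 17.0 to 8.94 percentage points without sham 2, for B cells, from 8.93 to 5.59 without sham 2, and for aerocytes, from -6.51 to -4.23 without healthy 1. This was also so for venous endothelium, from -3.46 to -1.50 without healthy 1 and -5.43 without healthy 2. Alveolar macrophages were 38.0 ± 13.1% and 13.6 ± 6.78% (adjusted p = 0.120), and the difference went from -24.4 to -15.2 without healthy 2. NK cells were 2.06 ± 0.593% and 2.65 ± 0.409% (0.746).

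In ultrasound animals B cells were 3.48 ± 2.08%, T cells 2.96 ± 1.88%, neutrophils 5.97 ± 0.220%, nonclassical monocytes 17.6 ± 3.88% and aerocytes 7.04 ± 3.89% of kept cells. No class passed edgeR's test on cell counts between ultrasound and sham (lowest adjusted p = 0.112) or, within pool 4, healthy animals (0.239). In no-isoflurane animals B cells were 11.8 ± 4.47%, T cells 9.83 ± 6.24% and neutrophils 6.08 ± 2.98%. Classical monocytes were 3.09 ± 2.71%, 5.67 ± 1.95%, 6.28 ± 0.327% and 5.44 ± 0.0712% in healthy, no-isoflurane, sham and ultrasound animals. In the same order interstitial macrophages were 1.67 ± 0.329%, 1.82 ± 0.192%, 1.83 ± 0.741% and 1.80 ± 1.01%. Permutation tests of the shares could not go below p = 0.333 with 2 animals against 2, and after adjustment none was below 0.481. Clusters left unnamed held 13.9 ± 5.62% of cells in healthy, 11.2 ± 1.83% in no-isoflurane, 6.97 ± 3.09% in sham and 11.1 ± 3.33% in ultrasound animals.

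**Figure D1:**
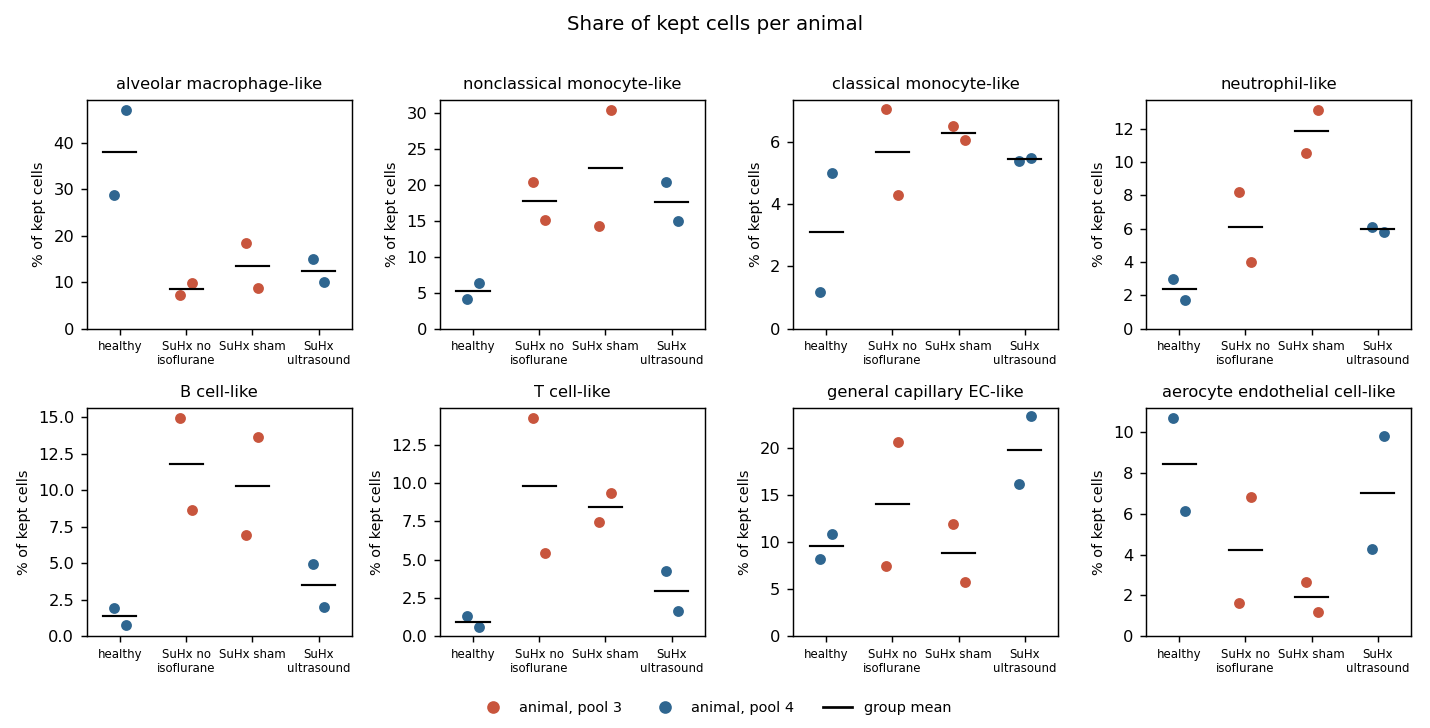
Share of each animal's kept cells (percent, vertical axis) in each cell class, by group (horizontal axis), with points for the 8 animals coloured by pool and lines for group means. Alveolar macrophages had a mean of 38.0% in healthy and 13.6% in sham animals.

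Sham SuHx animals were first compared with healthy animals, which asks what the disease model changed. In alveolar macrophages, the resident phagocytes of the air spaces, most NF-kB and inflammatory genes had higher estimates in sham SuHx animals, but the list calls did not hold with an estimated correlation (adjusted p = 0.328 and 0.328). Il1b (ENSRNOG00000004649), which encodes the cytokine interleukin 1 beta, rose from 195 ± 45.8 to 1384 ± 243 CPM, a log2 fold change of 2.82 ± 0.35 (adjusted p = 0.0275). The alarmin genes S100a8 and S100a9 rose by 1.67 ± 0.19 and 2.41 ± 0.30 (adjusted p = 0.00591 and 0.0155), but both also separated the pools. Of 9935 genes tested, 74 were higher and 21 lower at an adjusted p of 0.05.

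Of the 31 tested members of the NF-kB response list, 29 had a higher estimate, 5 passed over all genes and 19 adjusted over the list alone (median 0.71, adjusted p = 2.40e-23, adjusted p = 0.328 with an estimated correlation). The called genes were led by Plaur, the urokinase receptor (1.35 ± 0.15, adjusted p = 0.00591), and by the NF-kB subunits Relb (1.28 ± 0.14, 0.00591) and Nfkb1 (1.13 ± 0.14, 0.00768). In the list of inflammatory cytokines and chemokines 20 of 23 members had a higher estimate, with 4 higher over all genes and 6 higher and 2 lower adjusted over the list alone (median 0.92, adjusted p = 1.45e-07, adjusted p = 0.328 with an estimated correlation). Besides Il1b, these included Il1rn, the interleukin 1 receptor antagonist (1.2 ± 0.20, 0.0328), and the chemokine Ccl5 (0.78 ± 0.13, 0.0327). Immediate early genes were higher in 26 of 30, with 1 called over all genes and 9 higher and 1 lower adjusted over the list alone (median 0.76, adjusted p = 9.80e-10, adjusted p = 0.334 with an estimated correlation). The one called was Junb (1.25 ± 0.20, 0.0327). Nlrp3, the inflammasome sensor, had 1.82 ± 0.33 (adjusted p = 0.0709), Tnf 0.70 ± 0.31 (0.326), Ccl2 1.25 ± 1.17 (0.683) and Spp1 0.18 ± 0.79 (0.946), and none of these 4 passed.

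Among the hypoxia and glycolysis genes 2 of 22 passed over all genes and 4 adjusted over the list alone (median 0.14, adjusted p = 0.00443, adjusted p = 0.328 with an estimated correlation). They were Hif1a, the oxygen-regulated transcription factor (1.13 ± 0.12, adjusted p = 0.00550), and Egln1, the prolyl hydroxylase that marks it for breakdown (1.26 ± 0.22, 0.0328). Heat shock, alternative activation, MHC class II, antioxidant response and interferon response genes were higher (medians 0.35, 0.54, 0.29, 0.13 and 0.16, adjusted p = 0.00661, 0.0155, 0.0217, 0.0377 and 0.0483, adjusted p = 0.513, 0.328, 0.513, 0.560 and 0.513 with an estimated correlation). Single members called there were Il4r (1.61 ± 0.30, 0.0400) and Gbp5 (1.08 ± 0.20, 0.0380). Outside these lists, Pde4b, a phosphodiesterase that degrades cyclic AMP (1.55 ± 0.14, 0.00302), the interleukin 1 receptor kinase Irak2 (1.64 ± 0.17, 0.00550), and the cholesterol exporter Abca1 (0.86 ± 0.15, 0.0367) rose. RT1-CE1 rose too (1.13 ± 0.19, 0.0298). It is an MHC class I gene of a family whose reads can be split between copies, so its value is uncertain. Genes that fell were Tiam1 (by 3.08 ± 0.45, adjusted p = 0.0211), Atp10a (by 1.24 ± 0.17, 0.0155), the actin-severing protein gene Gsn (by 1.23 ± 0.19, 0.0252), and the TGF-beta receptor gene Tgfbr1 (by 0.85 ± 0.15, 0.0337). The immunoglobulin heavy chain gene Igh-6 fell by 3.04 ± 0.34 (0.00591) and is of a family with close copies, so its value is uncertain. The 16 tested genes linked to pulmonary arterial hypertension by human genetics had a median of 0.04, a test statistic in the opposite direction and no call (adjusted p = 0.955).

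Cells named alveolar macrophages came from cluster 5 and from cluster 6, which was led by Cxcl1, Il1a, Cxcl2 and Nlrp3. Cluster 6 held 5.0% and 2.75% of the class in the healthy animals and 64.1% and 53.1% in the sham animals. Neutrophil markers were higher in the class in 9 of 9 cases (median 1.08, adjusted p = 9.20e-12, adjusted p = 0.0207 with an estimated correlation). Igh-6, S100a8 and S100a9 also differed by pool. Igh-6 had 1.01 CPM or less in the 4 pool 3 animals and 6.22 CPM or more in the 4 pool 4 animals, whereas S100a8 had 22.7 CPM or more and 14.4 CPM or less, and S100a9 41.8 and 12.7 CPM. The count of 95 called genes became 63 without no-isoflurane 2, 31 without sham 1 and 39 without sham 2. Abca1, Ccl5, Egln1, Gbp5, Gsn, Il1b, Il4r, RT1-CE1, S100a9 and Tiam1 lost their calls without healthy 2 (adjusted p = 0.0516 to 0.156), as did Abca1, Ccl5, Egln1 and Gbp5 without no-isoflurane 1 or no-isoflurane 2 (0.0506 to 0.0726). Abca1, Atp10a, Ccl5, Egln1, Gbp5, Igh-6, Il1b, Il1rn, Il4r, Junb, RT1-CE1, Tgfbr1 and Tiam1 lost their calls without sham 1 (adjusted p = 0.0650 to 0.159), as did Abca1, Ccl5, Egln1, Gbp5, Gsn, Il1b, Il1rn, Il4r, Junb, Tgfbr1 and Tiam1 without sham 2 (0.0588 to 0.130). Abca1, Ccl5, Egln1, Gbp5, Gsn, Il1rn, Il4r, RT1-CE1 and Tgfbr1 lost their calls without ultrasound 1 (adjusted p = 0.0508 to 0.0629), as did Ccl5, Egln1, Il1rn, Il4r, RT1-CE1 and Tgfbr1 without ultrasound 2 (0.0531 to 0.0552). Egln1, Gbp5, Il1b, Il1rn, RT1-CE1, S100a9 and Tgfbr1 lost their calls without healthy 1 (adjusted p = 0.0526 to 0.102). The calls of Plaur, Relb, Nfkb1, S100a8, Hif1a, Pde4b and Irak2 held without any 1 of the 8 animals. With no-isoflurane animals in place of the sham animals Abca1, Egln1, Gbp5, Il1b, Il1rn, Il4r, Junb, Nfkb1, RT1-CE1, Tgfbr1 and Tiam1 lost their calls, and medians against healthy animals were 0.61 for NF-kB, 0.55 for inflammatory and 0.64 for immediate early genes. Fitting only the 2 groups ended the calls of Abca1, Atp10a, Ccl5, Egln1, Gbp5, Gsn, Il1rn, Il4r, Junb, S100a9 and Tgfbr1, thinning those of Ccl5, Egln1, Gbp5 and Il4r, joining sham and no-isoflurane animals those of Abca1 and Gbp5, keeping doublets that of S100a9, resolution 0.5 that of Ccl5, and 10% mitochondrial UMIs or less that of Abca1. At list level, calls were lost for alternative activation without any 1 of the 8 animals (adjusted p = 0.0823 to 0.246), and for the interferon response without healthy 2 or sham 1 (adjusted p = 0.163 and 0.975). Heat shock genes lost their call without healthy 1 (adjusted p = 0.492), and hypoxia genes without sham 1 (0.0508). MHC class II genes lost their call without healthy 1 or sham 1 (adjusted p = 0.144 and 0.159), and antioxidant genes without healthy 1 or sham 1 (0.413 and 0.470).

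In nonclassical monocytes most immediate early and NF-kB genes had higher and most interferon response genes lower estimates in sham than in healthy animals, but the list calls did not hold with an estimated correlation. The other SuHx group, without isoflurane, had medians against healthy animals of 0.04, 0.12 and -0.64 for these 3 lists, and 0.31 for Jun, 0.06 for Rhob and 0.63 for Nfkbia, with no call for these 3 genes. Of 46 tested interferon response genes 43 had a lower estimate, with 1 lower over all genes and 8 adjusted over the list alone (median -1.29, adjusted p = 6.20e-23, adjusted p = 0.279 with an estimated correlation). The one called over all genes was Oas2, an antiviral enzyme gene, which fell by 3.37 ± 0.67 (adjusted p = 0.0426). Its call held in 8 of 16 settings (adjusted p = 1.18e-06 to 0.650), and without healthy 2 it had -1.72. Immediate early genes were higher in 23 of 26, with 2 called over all genes and 14 adjusted over the list alone (median 0.56, adjusted p = 4.42e-11, adjusted p = 0.166 with an estimated correlation). Jun and Rhob rose by 1.03 ± 0.19 and 0.91 ± 0.17 (adjusted p = 0.0236 and 0.0221). In the NF-kB list 29 of 32 were higher, with 1 called over all genes and 5 adjusted over the list alone (median 0.66, adjusted p = 1.15e-09, adjusted p = 0.214 with an estimated correlation). Nfkbia (ENSRNOG00000007390), the feedback inhibitor of NF-kB, rose from 1331 ± 31.4 to 2888 ± 203 CPM (1.12 ± 0.14, adjusted p = 0.00403).

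The alarmin and neutrophil recruitment list was higher (median 0.36, adjusted p = 0.000382, adjusted p = 0.166 with an estimated correlation). In it the formyl peptide receptor gene Fpr2 rose by 1.47 ± 0.26 (adjusted p = 0.0221). Complement genes were higher (median 0.34, adjusted p = 0.000463, adjusted p = 0.174 with an estimated correlation), where Cfh rose by 1.06 ± 0.22 (0.0465). Heat shock, hypoxia and oxidative phosphorylation genes were higher (medians 0.22, 0.36 and 0.14, adjusted p = 8.66e-05, 0.00194 and 0.00386, adjusted p = 0.166, 0.279 and 0.570 with an estimated correlation). Vasoactive signalling genes were lower (median -1.15, adjusted p = 0.000744, adjusted p = 0.166 with an estimated correlation). Kdr and Cav1, typical of endothelium, had DESeq2 log2 folds of -2.61 and -2.32 without adjusted p, and endothelial RNA here was not tested. Cited2, a transcriptional co-regulator, rose by 1.84 ± 0.26 (0.00639), the lysosomal protease gene Ctsl by 2.17 ± 0.32 (0.00708) and the transglutaminase gene Tgm2 by 2.38 ± 0.43 (0.0221). Mylip rose by 1.32 ± 0.22 (0.0147) and RT1-CE1, uncertain as above, by 1.49 ± 0.26 (0.0458). The matrix protein gene Sparc fell by 3.17 ± 0.47 (0.00708), Srgap2 by 1.04 ± 0.17 (0.0130), Cers6 by 0.97 ± 0.17 (0.0221) and Chd6 by 0.93 ± 0.17 (0.0221), the values in brackets being adjusted p. Il1b, Nlrp3 and Ccl2 had 1.06 ± 0.48, 0.32 ± 0.34 and 0.79 ± 1.33 and did not pass (adjusted p = 0.457, 0.757 and 0.875). The 14 tested human PAH genes had a median of -0.17 (adjusted p = 0.311).

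In this class 22 genes were higher and 13 lower of 8561 tested. The count of 35 became 10 without healthy 1, 77 without healthy 2, 98 without no-isoflurane 1, 95 without no-isoflurane 2 and 11 without sham 2. Healthy 1 and healthy 2 contributed 32 and 74 cells. Markers of classical monocytes (median 0.80, adjusted p = 0.00221, adjusted p = 0.0945 with an estimated correlation) and of neutrophils (median 0.65, 0.00163 and 0.0945) were higher in the class in sham animals. Cluster 10, one of the 2 clusters of the class, held 21.9% and 24.3% of it in healthy and 53.1% and 59.0% in sham animals. Cers6, Cfh, Chd6, Fpr2, Jun, Mylip, Oas2, RT1-CE1, Rhob, Srgap2 and Tgm2 lost their calls without healthy 1. Cers6, Chd6, Oas2, RT1-CE1, Rhob and Srgap2 lost theirs without sham 1. Cers6, Cfh, Chd6, Fpr2, Jun, Oas2, RT1-CE1, Rhob and Tgm2 lost their calls without sham 2. Cfh, Chd6, Ctsl, Jun, Mylip, Oas2, RT1-CE1, Sparc and Tgm2 lost theirs without healthy 2. Hypoxia genes lost their call without healthy 1 or sham 2, and oxidative phosphorylation genes without healthy 1 or sham 1. Vasoactive signalling genes lost their call without healthy 2. The interferon, immediate early and NF-kB calls held without any 1 animal. With no-isoflurane in place of sham animals all 15 named genes lost their calls, though RT1-CE1, Fpr2, Cited2 and Cers6 still had log2 folds of 1.52, 1.43, 1.62 and -0.80. Thinning ended the calls of Cfh, Chd6, Cited2, Ctsl, Fpr2, Jun and Rhob, keeping doublets or resolution 0.5 those of Cfh, Oas2 and Tgm2, joining sham and no-isoflurane animals those of Cfh, Chd6, Ctsl, Jun, Mylip, Oas2, Rhob, Sparc and Tgm2, DESeq2 size factors those of Cfh and RT1-CE1, and fitting only the 2 groups that of Cfh. Classical monocytes and interstitial macrophages were not tested against healthy animals, because healthy 1 had fewer than 20 cells of each.

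In general capillary cells 93 genes were higher and 89 lower of 8649 between sham and healthy lungs. Aerocytes had 29 and 22 of 6569. In aerocytes Cyp1a1 (ENSRNOG00000019500), a cytochrome P450 induced through the aryl hydrocarbon receptor, rose from 20.5 ± 13.9 to 6011 ± 396 CPM (8.22 ± 0.33, adjusted p = 2.34e-18). Tiparp, another target of that receptor, rose by 3.69 ± 0.39 (2.91e-06). In general capillary cells the quinone reductase gene Nqo1 rose by 4.09 ± 0.27 (adjusted p = 1.74e-07) and the secreted protease gene Htra1 by 3.74 ± 0.34 (8.08e-06). The stem cell factor receptor gene Kit fell by 1.61 ± 0.16 in general capillary cells (adjusted p = 1.67e-05) and Nckap5 by 1.83 ± 0.17 (8.08e-06). The carbonic anhydrase gene Car2 and Lrrc34 fell in aerocytes by 2.05 ± 0.29 and 2.92 ± 0.46 (5.15e-05 and 0.000302). The count of 182 in general capillary cells became 74 without healthy 2 and 103 without sham 2, and that of 51 in aerocytes 33 without healthy 2 and 30 without sham 1. Of the genes named, the call of Lrrc34 was lost without sham 1 (adjusted p = 0.144). With sham and no-isoflurane animals joined, Lrrc34 and Tiparp lost their calls in aerocytes (-1.64 and 3.11) and Nqo1 in general capillary cells (3.57). With no-isoflurane in place of sham animals Lrrc34 had -1.21 and no call. In neutrophils edgeR called 0 of 3359 genes, with 470 at an unadjusted edgeR p under 0.05 and 39 called by DESeq2. The edgeR count became 237 without healthy 2, 3 without no-isoflurane 2, 7 without sham 1, 4 without ultrasound 1 and 4 without ultrasound 2.

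Ultrasound-treated SuHx animals were compared with sham SuHx animals, which differed from them by spleen stimulation and pool together. In nonclassical monocytes all 26 tested immediate early genes had lower estimates and 45 of 46 interferon response genes higher estimates in ultrasound animals. Jun (ENSRNOG00000026293) fell from 222 ± 17.3 to 105 ± 0.859 CPM (by 1.08 ± 0.15, adjusted p = 0.00544), against 111 ± 11.6 CPM in healthy animals. Fosb, which like Jun encodes a subunit of the AP-1 transcription factor, fell by 1.05 ± 0.15 (adjusted p = 0.00606) and the small GTPase gene Rhob by 0.81 ± 0.14 (0.0195). Nfkbia fell from 2888 ± 203 to 1669.6 ± 45.8 CPM (by 0.79 ± 0.14, adjusted p = 0.0195).

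Immediate early genes had 3 calls over all genes and 10 lower adjusted over the list alone (median -0.47, adjusted p = 2.19e-20, adjusted p = 0.232 with an estimated correlation). The NF-kB response list was lower in 27 of 32 members, with 1 called over all genes and 8 adjusted over the list alone (median -0.45, adjusted p = 4.52e-12, adjusted p = 0.232 with an estimated correlation). Inflammatory cytokines and chemokines were lower in 11 of 16, with no member called over all genes and 2 lower adjusted over the list alone (median -0.48, adjusted p = 0.000492, adjusted p = 0.232 with an estimated correlation). Their smallest p belonged to the chemokine genes Cxcl2 (-2.20 ± 0.34, adjusted p = 0.0899) and Ccl3 (-0.70 ± 0.16, 0.105), neither of which passed. Interferon response genes had no call over all genes and 3 higher adjusted over the list alone (median 0.73, adjusted p = 1.85e-12, adjusted p = 0.372 with an estimated correlation). Their members Cxcl10 (2.24 ± 0.45, adjusted p = 0.111) and Igtp (1.19 ± 0.30, 0.198) did not pass. MHC class I presentation and vasoactive signalling genes were higher (medians 0.23 and 0.43, adjusted p = 0.0263 and 0.00951, adjusted p = 0.584 and 0.232 with an estimated correlation). Hypoxia and glycolysis, heat shock and alarmin genes were lower (medians -0.26, -0.13 and -0.13, adjusted p = 0.000492, 0.00796 and 0.0263, adjusted p = 0.242, 0.242 and 0.242 with an estimated correlation). The peptide transporter gene Tap1 had 0.80 ± 0.18 (adjusted p = 0.0913). The matrix list did not pass. Of its members, Tgfb2 (TGF-beta 2) rose by 1.95 ± 0.25 (adjusted p = 0.00187) and Sparc by 2.42 ± 0.36 (0.00606). The endothelial genes Kdr, Cav1 and Vwf had DESeq2 log2 folds of 1.59, 1.58 and 1.17 without adjusted p, and endothelial RNA was not tested. Tgm2 fell by 1.23 ± 0.23 (0.0411). Il1b (-0.96 ± 0.44, 0.738), Nlrp3 (-0.61 ± 0.28, 0.686) and Ccl2 (-0.13 ± 0.79, 0.995) did not pass. The 14 tested human PAH genes had a median of 0.09 (adjusted p = 0.404).

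In nonclassical monocytes 2 genes were higher and 9 lower of 8561 tested, and DESeq2 called 17. The count of 11 became 17 without healthy 1, 17 without healthy 2, 46 without no-isoflurane 1, 41 without no-isoflurane 2, 20 without sham 1 and 18 without ultrasound 2. Fosb, Jun, Nfkbia, Rhob and Tgm2 lost their calls without ultrasound 1, as did Nfkbia, Rhob and Tgm2 without sham 1. Nfkbia, Rhob, Sparc and Tgm2 lost their calls without ultrasound 2, as did Rhob, Sparc and Tgm2 without sham 2. The call of Tgfb2 held without any 1 animal. MHC class I and alarmin genes lost their calls without sham 2 or ultrasound 1. Heat shock genes lost theirs without ultrasound 1, and hypoxia genes without sham 2. Markers of classical monocytes (median -0.57, adjusted p = 5.11e-05, adjusted p = 0.0434 with an estimated correlation) and of neutrophils (median -0.45, 2.55e-05 and 0.0434) were lower in the class in ultrasound animals. Cluster 10 held 24.6% and 43.1% of the class in ultrasound and 53.1% and 59.0% in sham animals. With the no-isoflurane animals in place of the sham animals, 4 genes were called and the list medians were 0.03 for immediate early genes, -0.04 for NF-kB and 0.11 for interferon response genes. None of the 7 named genes kept its call there (Jun -0.36, Tgfb2 0.42, Sparc 1.22), nor with sham and no-isoflurane animals joined. Thinning ended the calls of Fosb, Jun and Rhob, keeping doublets those of Fosb, Nfkbia and Tgm2, 10% mitochondrial UMIs or less those of Fosb and Tgm2, resolution 0.5 those of Nfkbia and Tgm2, and leaving out haemoglobin genes that of Tgm2.

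In classical monocytes, which enter inflamed tissue from the blood, 16 of 19 tested inflammatory genes had a lower estimate in ultrasound than in sham animals, 1 passed over all genes and 3 adjusted over the list alone (median -0.70, adjusted p = 3.62e-09, adjusted p = 0.129 with an estimated correlation). Il1a, which encodes interleukin 1 alpha, fell from 32.7 ± 6.18 to 3.51 ± 0.611 CPM (by 3.21 ± 0.47, adjusted p = 0.0208). The chemokine gene Ccl2 was at 840.2 ± 56.2 CPM in sham and 253 ± 109 CPM in ultrasound animals (-1.72 ± 0.44, adjusted p = 0.540) and did not pass. Neither did Il1b (-0.93 ± 0.51, 0.786) or Nlrp3 (-0.80 ± 0.36, 0.710). NF-kB genes were lower in 24 of 31, with no call over all genes and 3 lower adjusted over the list alone (median -0.42, adjusted p = 1.36e-07, adjusted p = 0.390 with an estimated correlation). Plaur and Nfkb1 had -0.54 ± 0.10 and -0.68 ± 0.14 (adjusted p = 0.0887 and 0.104). Interferon response genes were higher in 34 of 46 (median 0.63, adjusted p = 0.000136, adjusted p = 0.652 with an estimated correlation). None was called over all genes and 1 adjusted over the list alone, with Oasl2 at 1.36 ± 0.32 (0.138).

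The BMP and TGF-beta target list passed as lower (median -0.30, adjusted p = 0.000251, adjusted p = 0.286 with an estimated correlation). Of its 13 members 7 were lower, 1 called over all genes and 4 adjusted over the list alone. Id1, an inhibitor of differentiation induced by BMP, fell by 1.35 ± 0.21 (adjusted p = 0.0231). Hypoxia, immediate early and lipid and lysosome genes were lower (medians -0.24, -0.20 and -0.15, adjusted p = 0.000251, 0.000886 and 0.0330, adjusted p = 0.286, 0.327 and 0.503 with an estimated correlation). Alas1, the rate-limiting enzyme gene of haem synthesis, fell by 1.78 ± 0.26 (0.0279) and Phlda1 by 2.54 ± 0.42 (0.0279), and the mitochondrial carbonic anhydrase gene Ca5b rose by 2.04 ± 0.26 (0.0128). The 11 tested human PAH genes had a median of -0.01 (adjusted p = 0.160). These 5 genes were all those called of 7986. DESeq2 called 4 genes but not Id1, Il1a and Phlda1, thinning ended the calls of Il1a and Phlda1, and fitting only the 2 groups that of Phlda1. None of the 5 kept its call with sham and no-isoflurane animals joined or with no-isoflurane in place of sham animals, the latter with -1.77 for Il1a, -1.81 for Phlda1, -0.78 for Id1, -0.13 for Alas1 and 0.18 for Ca5b. Over all settings Il1a kept its call in 13 of 19 (adjusted p = 4.69e-07 to 0.627). The count of 5 became 19 without no-isoflurane 1, 22 without no-isoflurane 2, 50 without sham 1 and 13 without sham 2. Alas1, Ca5b, Id1, Il1a and Phlda1 lost their calls without ultrasound 1 or ultrasound 2 (adjusted p = 0.0661 to 0.239), as did Phlda1 without sham 2 (0.0793). NF-kB genes lost their call without ultrasound 1 (adjusted p = 0.0504), and immediate early genes without ultrasound 1 (0.191). Interferon genes lost their call without sham 1 or ultrasound 1 (adjusted p = 0.705 and 0.199), and lipid and lysosome genes without sham 2, ultrasound 1 or ultrasound 2 (0.558, 0.0837 and 0.0659).

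Alveolar macrophages of ultrasound animals had lower estimates than those of sham animals for most inflammatory genes, 19 of 23 (median -0.78, adjusted p = 5.29e-07, adjusted p = 0.513 with an estimated correlation). None was called over all genes and 3 were lower adjusted over the list alone. Il1b was at 1384 ± 243 CPM in sham, 732 ± 305 in ultrasound and 871 ± 163 in no-isoflurane animals. Its difference between ultrasound and sham animals did not pass (-0.92 ± 0.32, adjusted p = 0.811). The NF-kB list was lower in 25 of 31 (median -0.26, adjusted p = 9.70e-06, adjusted p = 0.606 with an estimated correlation), with 4 lower adjusted over the list alone. Nfkb1 and Nfkb2 had -0.73 ± 0.14 and -1.03 ± 0.19 (adjusted p = 0.273 and 0.273). Alarmin, MHC class II, cytotoxic lymphocyte and hypoxia genes were lower (medians -0.09, -0.46, -0.30 and -0.10, adjusted p = 0.00117, 0.0163, 0.0163 and 0.0470, adjusted p = 0.350, 0.606, 0.455 and 0.581 with an estimated correlation). Among members that did not pass, S100a9 and S100a8 had -2.45 ± 0.32 and -1.11 ± 0.19 (adjusted p = 0.0762 and 0.252), Ccl5 -0.82 ± 0.14 (0.20) and Hif1a -0.66 ± 0.12 (0.254). Nlrp3 (-0.87 ± 0.33, 0.822), Spp1 (-2.47 ± 0.88, 0.840), Ccl2 (-0.92 ± 1.22, 0.949) and Tnf (0.23 ± 0.31, 0.949) did not pass. The 16 tested human PAH genes had a median of 0.02 (adjusted p = 0.132).

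Of 9935 genes tested in alveolar macrophages 1 was higher and 2 were lower. The higher one was Igh-6 (2.93 ± 0.36, adjusted p = 0.0388), which also differed by pool. Its call was lost without any 1 of the 8 animals (adjusted p = 0.0602 to 0.234) and held in 7 of 20 settings. The lower ones were haemoglobin genes, and Hba-a1 had 16.1 CPM or more in the pool 3 animals and 0.75 CPM or less in the pool 4 animals. DESeq2 called 15 genes, and the count became 6 without sham 1, 5 without sham 2 and 5 without ultrasound 1. Neutrophil markers were lower in the class in ultrasound animals (median -0.69, adjusted p = 1.35e-08, adjusted p = 0.0381 with an estimated correlation), and cluster 6 held 13.4% and 35.3% of it. Without ultrasound 1 the list calls of NF-kB (adjusted p = 0.236), MHC class II (0.297) and cytotoxic lymphocyte genes (0.0649) were lost. MHC class II also lost its call without sham 1 (adjusted p = 0.283), and hypoxia lost its call when any 1 of the animals other than sham 2 was left out (0.0545 to 0.322).

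In interstitial macrophages, a small class whose cluster also expressed the dendritic cell genes Clec10a and Ccl17, Slpi, a secreted protease inhibitor, was the one gene called of 7092. It rose from 377 ± 127 to 2011 ± 448 CPM (2.40 ± 0.30, adjusted p = 0.0290), and its call was lost without sham 2 or ultrasound 1 (adjusted p = 0.0690 to 0.124) and with only the 2 groups fitted. Among genes that did not pass, Plet1 and Satb1 had the smallest p of the lower ones (-2.70 ± 0.44 and -3.26 ± 0.57, adjusted p = 0.178 and 0.247). Il1b (-0.97 ± 0.43, 0.955), Nlrp3 (-0.68 ± 0.38, 0.993) and Ccl2 (-0.66 ± 1.0, 0.993) did not pass. Vasoactive, interferon response, lipid and lysosome and PAH genes were higher (medians 0.75, 0.21, 0.37 and 0.58, adjusted p = 1.53e-05, 0.00378, 0.00522 and 0.0106, adjusted p = 0.821, 0.821, 0.829 and 0.821 with an estimated correlation). Cell cycle and NF-kB genes were lower (medians -1.37 and -0.40, adjusted p = 0.000252 and 0.00193, adjusted p = 0.821 and 0.821 with an estimated correlation). Of the 13 PAH genes 9 had a higher estimate, with 0 called over all genes and 0 adjusted over the list alone. The PAH list lost its call without healthy 2, sham 2 or ultrasound 2 (adjusted p = 0.239, 0.475 and 0.888), and the cell cycle list without sham 1 or ultrasound 1 (0.844 and 0.0993). The NF-kB list lost its call without sham 1 or ultrasound 2 (adjusted p = 0.994 and 0.153), and the interferon list without sham 2 or ultrasound 2 (0.20 and 0.153). The lipid list lost its call without sham 2 or ultrasound 1 (adjusted p = 0.673 and 0.955). T cell markers were lower in the class (median -4.16, adjusted p = 1.06e-08, adjusted p = 0.151 with an estimated correlation) and capillary endothelial markers higher (median 1.41, 8.19e-05 and 0.151).

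In NK cells 246 genes were higher and 67 lower of 6036 between ultrasound and sham animals. This was the most of any class tested, but with doublets kept the count was 15, under the 20 of classical monocytes, and Ccl4 and Ramp2 lost their calls (-1.30 and 1.45). DESeq2 called 171. Adgrl3, an adhesion receptor gene, had 0 UMIs in the sham and 99 in the ultrasound animals, at least 56.9-fold higher against a floor of 3 counts over the sham group. Ramp2, a receptor partner typical of endothelium, rose by 4.36 ± 0.42 (adjusted p = 4.22e-07). The chemokine gene Ccl4 fell by 1.41 ± 0.20 (9.03e-05) and the kinase gene Camk4 by 2.28 ± 0.28 (8.08e-06). Markers of general capillary endothelium were higher in the class in 8 of 8 cases (median 4.94, adjusted p = 8.54e-18, adjusted p = 0.0825 with an estimated correlation). The count of 313 became 472 without no-isoflurane 1, 173 without sham 1 and 154 without sham 2. In B cells the chemokine gene Ccl3 fell by 1.38 ± 0.21 (adjusted p = 0.0367), and Dach1 and Zeb2 rose by 3.41 ± 0.59 and 1.0 ± 0.18 (0.0378 and 0.0378). Aerocyte markers were higher there (median 2.18, adjusted p = 3.34e-06, adjusted p = 0.114 with an estimated correlation). The 5 calls in B cells became 90 without sham 1, 41 without sham 2 and 8 without ultrasound 1. Ccl3, Dach1 and Zeb2 lost their calls without ultrasound 2, as did Dach1 and Zeb2 without ultrasound 1. Zeb2 lost its call without no-isoflurane 1 or no-isoflurane 2. With doublets kept all 3 lost their calls (-0.64, 2.81 and 0.00337), and at 10% mitochondrial UMIs or less Ccl3 and Zeb2. Thinning ended the calls of Dach1 and Zeb2, and fitting only the 2 groups or no-isoflurane in place of sham animals that of Zeb2. In general capillary cells Lyz2 and the glutathione peroxidase gene Gpx2 rose by 0.94 ± 0.16 and 1.26 ± 0.22 (adjusted p = 0.0202 and 0.0473), and the substance P receptor gene Tacr1 fell by 4.30 ± 0.69 (0.0483). The 9 calls there became 5 without sham 2 and 18 without ultrasound 2, and 1 without haemoglobin genes or at 10% mitochondrial UMIs or less. Over all settings Lyz2 kept its call in 12 of 20, Gpx2 in 9 of 20 and Tacr1 in 8 of 19. Gpx2 and Tacr1 lost their calls without healthy 1 or healthy 2 or ultrasound 1 (adjusted p = 0.0707 to 0.268), as did Gpx2 without no-isoflurane 2 (0.0531). Gpx2, Lyz2 and Tacr1 lost their calls without sham 2, as did Lyz2 without sham 1. Lyz2 and Tacr1 lost their calls without ultrasound 2. In T cells edgeR called 0 of 7995 genes, with 667 at an unadjusted edgeR p under 0.05 and 2 called by DESeq2. The edgeR count became 3 without no-isoflurane 1, 3 without no-isoflurane 2, 9 without sham 1, 2 without sham 2, 64 without ultrasound 1 and 16 without ultrasound 2.

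**Figure D2:**
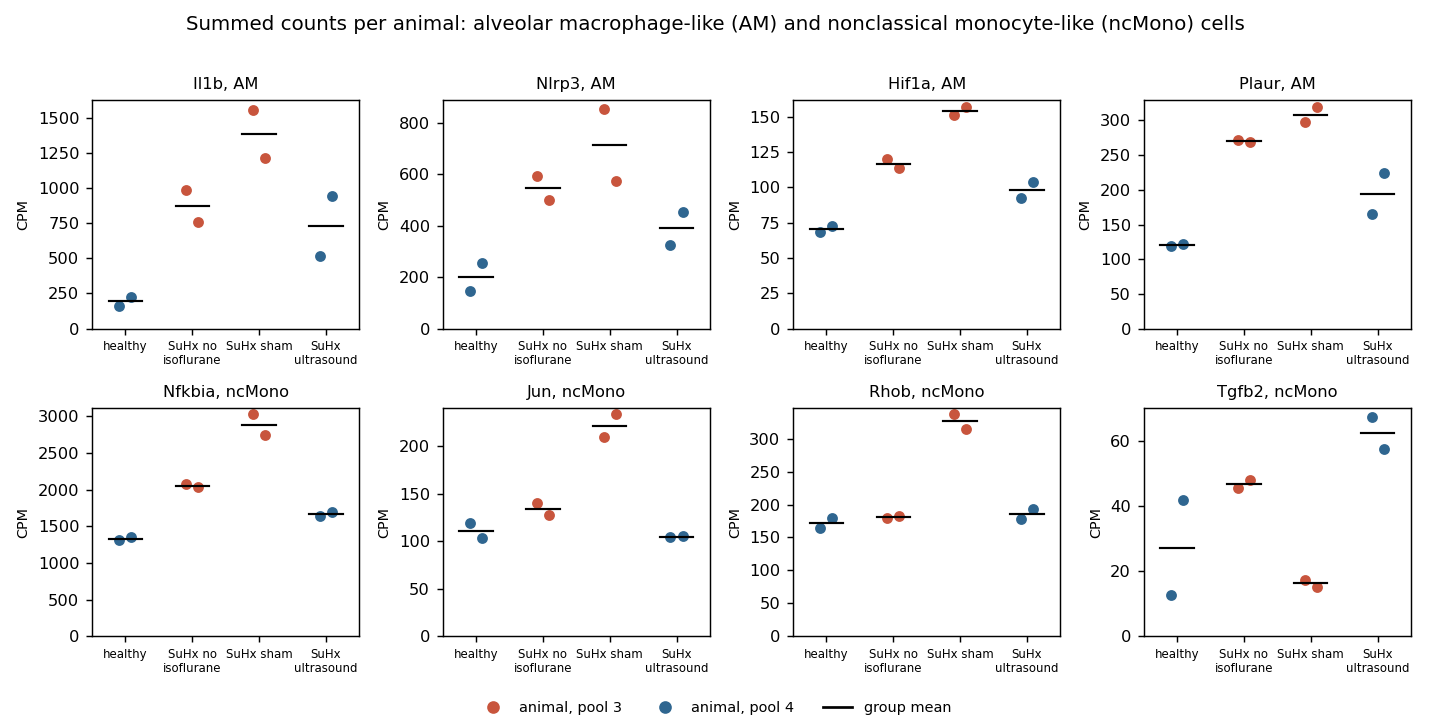
CPM (vertical axis) of named genes in monocyte and macrophage classes of each animal, by group (horizontal axis). Points are animals coloured by pool and lines are group means.

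Genes that differed between sham and healthy animals were then followed in the ultrasound comparison. In alveolar macrophages 90 of the 95 genes called in sham against healthy (94.7%) had the opposite sign in ultrasound against sham, and in nonclassical monocytes 34 of 35 (97.1%). Both comparisons share the sham animals, and in 50 simulations with unchanged ultrasound animals the share was 68.7% (95% range 66.6% to 71.4%) and 65.5% (61.6% to 69.0%). The covariance of the 2 sets of fold changes over all tested genes was -0.131 in alveolar macrophages against -0.0637 simulated, and -0.167 in nonclassical monocytes against -0.0584. Splitting the sham animals would leave fewer than 2 in each part, and the simulations may understate their noise. The excess may thus come wholly from sharing, and both comparisons also cross the pools in opposite directions. With no-isoflurane against healthy as the first comparison, which shares no animal with ultrasound against sham, 28 of 34 called genes (82.4%) had the opposite sign in alveolar macrophages, and the covariances were -0.0669 and -0.0704. These comparisons also cross the pools in opposite directions, and no value without a change was simulated for them. In nonclassical monocytes edgeR called 0 genes in that first comparison, with 854 at an unadjusted edgeR p under 0.05.

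Ultrasound animals were also compared with healthy animals, all within pool 4. In alveolar macrophages 28 of 30 immediate early and 26 of 31 NF-kB genes had higher estimates in ultrasound than in healthy animals. Cluster 6 held 5.0% and 2.75% of the class in healthy and 13.4% and 35.3% in ultrasound animals. Immediate early, NF-kB, heat shock, interferon response and alternative activation genes were higher (medians 0.76, 0.59, 0.31, 0.27 and 0.43, adjusted p = 5.03e-15, 1.75e-14, 9.32e-06, 0.000684 and 0.0237, adjusted p = 0.389, 0.389, 0.415, 0.415 and 0.389 with an estimated correlation). Lipid and lysosome, matrix and oxidative phosphorylation genes were lower (medians -0.25, -0.25 and -0.09, adjusted p = 0.0226, 0.0237 and 0.0237, adjusted p = 0.681, 0.415 and 0.758 with an estimated correlation). Il1b had 1.90 ± 0.33 (adjusted p = 0.180) and did not pass. In nonclassical monocytes, of which cluster 10 held 21.9% and 24.3% in healthy and 24.6% and 43.1% in ultrasound animals, 40 of 46 interferon response genes were lower (median -0.70, adjusted p = 8.29e-07, adjusted p = 0.682 with an estimated correlation). Oxidative phosphorylation, alarmin and complement genes were higher (medians 0.17, 0.24 and 0.23, adjusted p = 8.79e-05, 0.0287 and 0.0368, adjusted p = 0.627, 0.530 and 0.530 with an estimated correlation). In arterial endothelium 102 genes were higher and 67 lower of 6455, in general capillary cells 37 and 34, in aerocytes 16 and 12 and in venous endothelium 4 and 1. Cyp1a1 rose by 8.10 ± 0.33 in aerocytes (adjusted p = 3.27e-18) and by 6.62 ± 0.63 in venous endothelium (0.0137), and Nqo1 by 3.19 ± 0.28 in general capillary cells (1.29e-05) and 4.30 ± 0.37 in arterial endothelium (2.10e-05).

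Alveolar macrophages had 5 called genes in this comparison and 95 by DESeq2. The count became 36 without healthy 1, 28 without healthy 2, 2 without no-isoflurane 1, 0 without no-isoflurane 2, 9 without sham 1, 9 without sham 2, 17 without ultrasound 1 and 2 without ultrasound 2. In nonclassical monocytes edgeR called 0 genes, with 671 at an unadjusted edgeR p under 0.05 and 2 by DESeq2. The edgeR count became 1 without healthy 1, 1 without healthy 2, 8 without no-isoflurane 1, 8 without no-isoflurane 2, 3 without sham 2 and 2 without ultrasound 1. The 169 calls in arterial endothelium became 43 without healthy 1, 95 without healthy 2, 283 without no-isoflurane 1, 313 without no-isoflurane 2, 82 without ultrasound 1 and 99 without ultrasound 2. Those in general capillary cells, 71, became 19 without healthy 2 and 39 without ultrasound 2. The 28 in aerocytes became 18 without healthy 1, 43 without sham 2 and 13 without ultrasound 2 and the 5 in venous endothelium 20 without healthy 1, 28 without healthy 2, 3 without sham 1, 16 without ultrasound 1 and 14 without ultrasound 2. In alveolar macrophages the list call of alternative activation was lost without any 1 animal (adjusted p = 0.0803 to 0.804). Oxidative phosphorylation genes lost their call without healthy 2, no-isoflurane 1, no-isoflurane 2, sham 1 or ultrasound 2, and lipid genes without healthy 2. Matrix genes lost their call without healthy 2 or sham 1. In nonclassical monocytes interferon genes lost their call without healthy 2 (adjusted p = 0.162). Oxidative phosphorylation genes there lost their call without healthy 1, and alarmin genes without healthy 1 or ultrasound 2. Complement genes lost their call without healthy 1 or ultrasound 2.

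**Figure D3:**
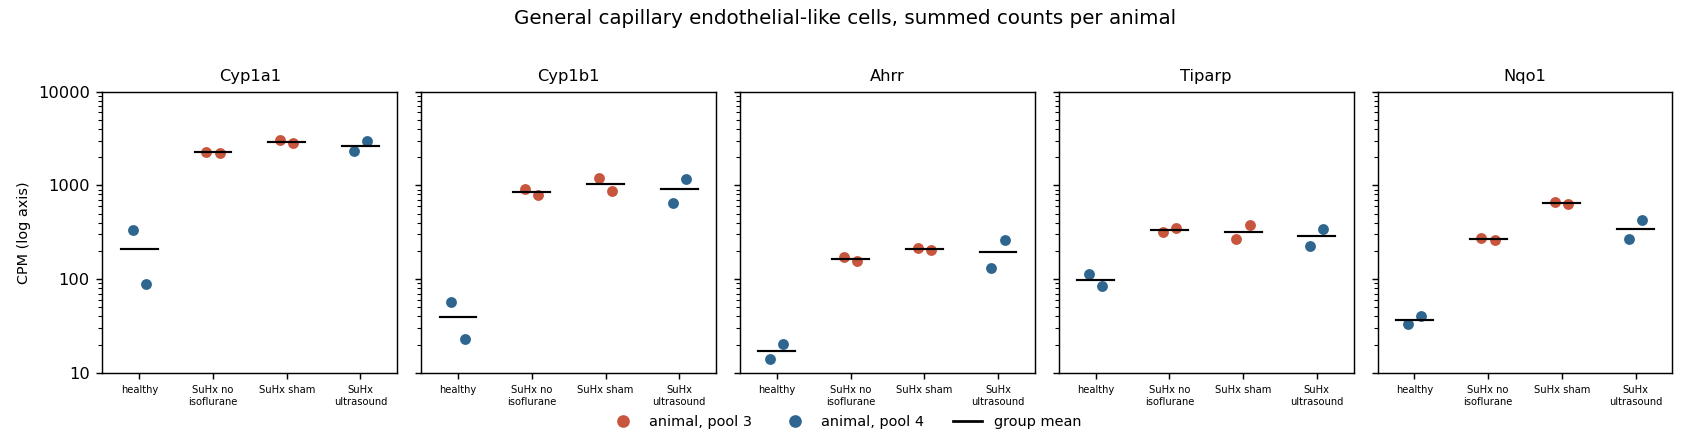
CPM (vertical axis, log scale) of genes of xenobiotic metabolism in general capillary endothelial cells of each animal, by group (horizontal axis). Points are animals coloured by pool and lines are group means, with the 2 healthy animals below the SuHx animals.

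Sham animals were also compared with no-isoflurane SuHx animals of the same pool, a comparison added after the tag table had been read. In nonclassical monocytes 10 lists passed, of which 6 had also passed between ultrasound and sham animals. Both comparisons share the sham animals, so opposite directions are partly built in, and no value without a change was computed. Cluster 10 held 32.1% and 24.1% of the class in no-isoflurane animals and 53.1% and 59.0% in sham animals. All 26 immediate early genes had higher estimates in sham animals, with 1 called over all genes and 17 adjusted over the list alone (median 0.54, adjusted p = 3.04e-21, adjusted p = 0.147 with an estimated correlation). NF-kB genes were higher in 26 of 32, 12 of them adjusted over the list alone (median 0.37, adjusted p = 1.23e-10, adjusted p = 0.230 with an estimated correlation). Interferon response genes were lower in 44 of 46 (median -0.66, adjusted p = 3.25e-10, adjusted p = 0.436 with an estimated correlation). Inflammatory and heat shock genes were higher (medians 0.49 and 0.10, adjusted p = 5.0e-05 and 0.0186, adjusted p = 0.160 and 0.349 with an estimated correlation). MHC class I genes were lower (median -0.27, adjusted p = 1.50e-06, adjusted p = 0.349 with an estimated correlation). The 4 others, lipid and lysosome, alternative activation, complement and antioxidant genes, were higher (medians 0.09, 0.47, 0.30 and 0.24, adjusted p = 0.000668, 0.000246, 0.00236 and 0.000434, adjusted p = 0.147, 0.160, 0.255 and 0.349 with an estimated correlation). In classical monocytes, alveolar macrophages and interstitial macrophages 5, 5 and 6 lists passed, and the one with the smallest p is given for each. In classical monocytes interferon response genes were lower (median -0.74, adjusted p = 1.38e-09, adjusted p = 0.448 with an estimated correlation). In alveolar macrophages cell cycle genes were higher (median 0.61, adjusted p = 4.88e-06, adjusted p = 0.462 with an estimated correlation). In interstitial macrophages lipid and lysosome genes were lower (median -0.81, adjusted p = 2.01e-08, adjusted p = 0.950 with an estimated correlation). Cluster 6 held 38.9% and 43.7% of alveolar macrophages in no-isoflurane and 64.1% and 53.1% in sham animals. Classical monocyte markers were higher in nonclassical monocytes (median 0.66, adjusted p = 5.79e-05, adjusted p = 0.0789 with an estimated correlation), and T cell markers in classical monocytes (median 2.21, 5.11e-08 and 0.0833) and interstitial macrophages (median 3.81, 4.37e-10 and 0.196). In nonclassical monocytes 7 genes were called, a count that became 36 without no-isoflurane 1, 22 without no-isoflurane 2 and 22 without sham 1. In alveolar macrophages edgeR called 0 genes, with 375 at an unadjusted edgeR p under 0.05 (497 expected by chance) and 0 by DESeq2. Without no-isoflurane 2 the interferon list's test pointed to higher in both monocyte classes (adjusted p = 0.235 in nonclassical and 0.902 in classical monocytes). Inflammatory genes lost their call without no-isoflurane 1 (adjusted p = 0.0637), and MHC class I genes without no-isoflurane 2 (0.369). Heat shock genes there lost their call without no-isoflurane 1 or sham 1 (adjusted p = 0.117 and 0.0832), and alternative activation genes without no-isoflurane 1 (0.0822). Complement genes lost their call without sham 2 (adjusted p = 0.278), and antioxidant genes without no-isoflurane 2 (0.0564). Interferon genes in classical monocytes also lost their call without sham 1 (adjusted p = 0.257). Lipid genes in interstitial macrophages lost their call without no-isoflurane 1 (adjusted p = 0.129).

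Summed over all kept cells of an animal, where composition and expression both count, edgeR called 1 gene of 14263 in sham against healthy and 0 in ultrasound against sham, ultrasound against healthy and sham against no isoflurane. At an unadjusted edgeR p under 0.05 there were 2793, 1195, 1993 and 425 genes, and DESeq2 called 1095, 69 and 435 in the first 3 of these comparisons.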

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

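The share of endothelial genes among the NK calls was chosen as a test after the result was seen, whereas the removal of mixed cells was set down before its result. In ultrasound against sham animals Id1 fell in classical monocytes (-1.35) and rose in NK cells (3.78), a difference of -5.13 on the log2 scale that was not tested itself. Rhob rose in NK cells (1.12) and fell in nonclassical monocytes (-0.81), a difference of 1.94 that was not tested either. Cluster 21, left unnamed and outside every comparison of genes, was led by the cytotoxic genes Ccl5, Ctsw, Gzmm, Gzmk, Nkg7 and Faslg. It held 5.09% of kept cells in no-isoflurane animals (4.14% and 6.05%), 1.57% in sham, 0.486% in ultrasound and 0.347% in healthy animals.

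Of the 246 genes called higher in NK cells of ultrasound animals, 65.4% had at least 4 times the level in the endothelial classes, against 5.88% of all tested genes and 0% of those called lower. The 50 genes most abundant in endothelium were taken among those much higher there than in NK cells of sham and no-isoflurane animals. Their excess in NK cells of ultrasound animals over those NK cells had a median of 11% of the endothelial level. It was 7.47% in ultrasound 1 and 14.6% in ultrasound 2. Endothelial marker UMIs were found in 62.1% and 64.5% of NK cells of ultrasound animals and in 22.0% and 29.2% of those of sham animals. Healthy animals, of the ultrasound pool, had them in 42.1% and 68.4% of 19 cells each, and no-isoflurane animals in 45.6% and 29.7%. Ultrasound animals thus did not stand apart from healthy ones. Removing cells with at least 2 such UMIs left 19 cells in ultrasound 2, too few to test again. With doublets kept 15 genes were called, not 313. Endothelial RNA or attached cells may account for many of the higher calls, but the share lay below that set for this reading. A pool difference or an effect of stimulation stays open.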

How the results depend on the processing

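Settings that join, exchange or replace the sham animals, or leave out haemoglobin genes, were chosen after the results were seen. No pool term could be fitted, so the planned fits with one were not run, and no paired analysis was possible because the animals of different groups share no numbers in the labels. Of 1299 refits of the 69 named calls (1 gene in 1 class and comparison) 993 kept the call, leaving out 7 without a DESeq2 adjusted p, and across named genes 2107 of 2312 fits without 1 animal kept their side of the threshold. Where an animal was left out the other of its group was taken to vary like the other groups. Counts of called genes stayed within 1.5 times in 98 of 218 fits without 1 animal and 181 of 298 others. For every value that changed, the cause was not tested.

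With no filter on low counts counts were, for sham against healthy 95 in aerocytes, 720 in alveolar macrophages, 360 in general capillary cells, 80 in neutrophils, 284 in nonclassical monocytes and 277 in the whole lung, for ultrasound against sham 17 in aerocytes, 133 in alveolar macrophages, 154 in B cells, 119 in classical monocytes, 87 in general capillary cells, 82 in interstitial macrophages, 31 in neutrophils, 567 in NK cells, 146 in nonclassical monocytes and 128 in T cells, for ultrasound against healthy 63 in aerocytes, 343 in alveolar macrophages, 270 in arterial endothelium, 204 in general capillary cells, 5 in neutrophils, 37 in nonclassical monocytes, 30 in venous endothelium and 15 in the whole lung, for sham against no isoflurane 41 in alveolar macrophages, 66 in classical monocytes, 61 in interstitial macrophages and 131 in nonclassical monocytes. After thinning to the lowest total counts were, for sham against healthy 31 in aerocytes and 9 in neutrophils, for ultrasound against sham 0 in aerocytes, 3 in B cells, 4 in general capillary cells, 0 in neutrophils and 3 in nonclassical monocytes, for ultrasound against healthy 3 in aerocytes, 3 in alveolar macrophages and 21 in venous endothelium, for sham against no isoflurane 0 in interstitial macrophages and 2 in nonclassical monocytes. With sham and no-isoflurane animals joined counts were, for sham against healthy 92 in aerocytes, 233 in alveolar macrophages, 16 in nonclassical monocytes and 829 in the whole lung, for ultrasound against sham 0 in aerocytes, 5 in alveolar macrophages, 34 in B cells, 0 in classical monocytes, 2 in interstitial macrophages, 5 in neutrophils and 2 in nonclassical monocytes. With only the 2 groups compared counts were, for sham against healthy 49 in alveolar macrophages, 4 in neutrophils, 80 in nonclassical monocytes and 0 in the whole lung, for ultrasound against sham 2 in aerocytes, 1 in alveolar macrophages, 0 in interstitial macrophages, 0 in neutrophils and 20 in nonclassical monocytes, for ultrasound against healthy 5 in nonclassical monocytes and 3 in venous endothelium, for sham against no isoflurane 2 in classical monocytes and 11 in nonclassical monocytes. With doublets kept counts were, for sham against healthy 3 in the whole lung, for ultrasound against sham 0 in aerocytes, 0 in B cells, 20 in classical monocytes, 4 in general capillary cells, 4 in neutrophils, 15 in NK cells and 2 in T cells. At 10% mitochondrial UMIs or less counts were, for ultrasound against sham 2 in aerocytes, 1 in alveolar macrophages, 0 in B cells, 17 in classical monocytes, 1 in general capillary cells, 2 in neutrophils and 3 in T cells, for ultrasound against healthy 1 in alveolar macrophages. With the DESeq2 Wald test counts were, for sham against healthy 243 in alveolar macrophages, 39 in neutrophils, 97 in nonclassical monocytes and 1095 in the whole lung, for ultrasound against sham 0 in aerocytes, 15 in alveolar macrophages, 17 in B cells, 3 in interstitial macrophages, 0 in neutrophils, 171 in NK cells, 17 in nonclassical monocytes, 2 in T cells and 69 in the whole lung, for ultrasound against healthy 17 in aerocytes, 95 in alveolar macrophages, 100 in arterial endothelium, 2 in nonclassical monocytes and 435 in the whole lung, for sham against no isoflurane 15 in nonclassical monocytes. With no-isoflurane in place of sham animals counts were, for sham against healthy 34 in alveolar macrophages, 79 in general capillary cells, 0 in nonclassical monocytes and 0 in the whole lung, for ultrasound against sham 0 in aerocytes, 23 in B cells, 1 in classical monocytes, 162 in NK cells, 4 in nonclassical monocytes and 2 in T cells. With at least 50 cells per animal counts were, for ultrasound against sham 2 in neutrophils and 17 in nonclassical monocytes, for ultrasound against healthy 44 in aerocytes. Without haemoglobin genes counts were, for ultrasound against sham 0 in alveolar macrophages and 1 in general capillary cells. At resolution 0.5 counts were, for ultrasound against sham 23 in classical monocytes and 4 in general capillary cells, for ultrasound against healthy 10 in venous endothelium.

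With an estimated correlation 0 lists passed in every class and comparison in which any did. The test with edgeR on cell counts put 6 class shares of sham against healthy past the threshold that permutation could not reach, with log2 folds of 2.94 in B cells, 3.17 in T cells, -2.13 in aerocytes, 2.34 in neutrophils, 2.07 in nonclassical monocytes and -2.77 in venous endothelium. Differences in share, in percentage points, changed sign under 3 settings. Among immune cells only they became -0.611 for NK cells (sham against healthy), -0.587 for interstitial macrophages (sham against healthy), 0.281 for NK cells (ultrasound against sham), 5.32 for alveolar macrophages (ultrasound against sham), 2.51 for classical monocytes (ultrasound against sham), 0.828 for interstitial macrophages (ultrasound against sham) and 5.86 for nonclassical monocytes (ultrasound against sham). At resolution 0.5 they became -0.0637 for interstitial macrophages (sham against healthy) and 0.152 for interstitial macrophages (ultrasound against sham). At 10% mitochondrial UMIs or less they became 0.0395 for interstitial macrophages (ultrasound against sham) and 0.157 for NK cells (ultrasound against healthy). Rhob in nonclassical monocytes had a log2 fold change of 0.0384 with no-isoflurane in place of sham animals, against a fall from sham, and did not pass. At an unadjusted edgeR threshold of 0.01 the share of genes of opposite sign was 88.7% in alveolar macrophages and 93.7% in nonclassical monocytes. With no-isoflurane animals in the first comparison it was 70.0% and 72.0%.

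Without 1 animal at a time the gene counts ranged, for sham against healthy 30 to 66 in aerocytes, 31 to 108 in alveolar macrophages, 74 to 226 in general capillary cells, 0 to 237 in neutrophils, 10 to 98 in nonclassical monocytes and 0 to 3 in the whole lung, for ultrasound against sham 4 to 90 in B cells, 154 to 472 in NK cells, 2 to 64 in T cells, 0 to 5 in aerocytes, 2 to 6 in alveolar macrophages, 5 to 50 in classical monocytes, 5 to 18 in general capillary cells, 1 to 2 in interstitial macrophages, 0 to 14 in neutrophils, 11 to 46 in nonclassical monocytes and 0 to 1 in the whole lung, for ultrasound against healthy 13 to 43 in aerocytes, 0 to 36 in alveolar macrophages, 43 to 313 in arterial endothelium, 19 to 79 in general capillary cells, 0 to 186 in neutrophils, 0 to 8 in nonclassical monocytes, 3 to 28 in venous endothelium and 0 to 1 in the whole lung, for sham against no isoflurane 0 to 1 in alveolar macrophages, 2 to 47 in classical monocytes, 0 to 7 in interstitial macrophages and 6 to 36 in nonclassical monocytes. Lists passed ranged, for sham against healthy 4 to 10 in alveolar macrophages, for ultrasound against sham 5 to 10 in alveolar macrophages, 4 to 8 in classical monocytes and 3 to 7 in interstitial macrophages, for ultrasound against healthy 5 to 9 in alveolar macrophages, for sham against no isoflurane 1 to 7 in alveolar macrophages. Differences in share whose sign changed ranged, in percentage points, for sham against healthy -3.82 to 2.39 in general capillary cells and -0.359 to 0.689 in interstitial macrophages, for ultrasound against sham -5.88 to 3.70 in alveolar macrophages, -0.513 to 2.82 in arterial endothelium, -0.746 to 0.677 in interstitial macrophages and -12.8 to 3.41 in nonclassical monocytes, for ultrasound against healthy -0.567 to 0.272 in NK cells, -4.14 to 1.37 in aerocytes, -2.34 to 0.638 in arterial endothelium and -0.581 to 0.842 in interstitial macrophages.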

Other observations

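The tests of pools, free RNA and dissociation here were chosen after the results were seen. The second list of receptor targets was set before its values were seen. In general capillary cells a set of genes of xenobiotic metabolism was higher in all 6 SuHx animals than in the 2 healthy ones. Cyp1b1, a cytochrome P450, rose from 39.7 ± 24.0 to 1032 ± 216 CPM (SD, n = 2) in sham animals (4.90 ± 0.45, edgeR adjusted p = 0.000987), Ahrr, the repressor of the aryl hydrocarbon receptor, from 17.3 ± 4.41 to 209.9 ± 5.31 CPM (3.51 ± 0.45, 0.00170), and Tiparp by 1.72 ± 0.27 (0.00234). Cyp1a1 rose by 3.94 ± 0.54 in sham (0.0271) and had 3.80 ± 0.54 in ultrasound animals, which did not pass (0.0539). None of these genes or Nqo1 passed between ultrasound and sham animals, but within pool 3 Nqo1 was higher in sham than in no-isoflurane animals (1.28 ± 0.19, 0.0204).

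A pool difference as the whole cause is argued against by values within pool 4. There 4 of the 5 genes were called higher in ultrasound than in healthy animals. Free RNA shared by all cells is argued against by the level of Cyp1a1 in alveolar macrophages of SuHx animals, 0.293% of that in general capillary cells. Activity of the aryl hydrocarbon receptor in SuHx endothelium is a hypothesis that stays open. All 5 genes were called higher in sham animals. Of 3 tested genes of the second list only Nfe2l2 was (0.84 ± 0.20, adjusted p = 0.0331), where at least 2 were asked for. Ugt1a6 and Xdh had -0.77 ± 0.80 and -0.61 ± 0.28. The model's compound could induce such genes, through the receptor or otherwise, which was not tested.

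Immediate early genes in nonclassical monocytes had lower estimates in ultrasound than in sham animals, with 3 of 26 called and a list call that did not hold with an estimated correlation (adjusted p = 0.232), and the pools are a candidate cause because these groups lay in different ones. Ultrasound against no-isoflurane animals crosses the pools as well, and there the median was 0.0315, against -0.47 for ultrasound against sham, which argues against the pools as the whole cause. A response of all cells to dissociation, of like size in every class, is argued against by medians of 0.141 in general capillary cells, 0.05 in alveolar and 0.07 in interstitial macrophages. One in some cell types only stays open, with -0.202 in classical monocytes, -0.36 in B cells and -0.24 in T cells. Within pool 3 sham animals had a median 0.54 above no-isoflurane animals, so the difference may belong to the sham animals or their handling, such as anaesthesia, as much as to ultrasound, and these cannot be told apart with 2 animals per group.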
